A study of Mus musculus with 9 samples.

How the data were processed

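RNA of cells that the labels name HL-1, an immortalized mouse atrial cardiomyocyte line, was measured on 9 Affymetrix mouse transcript arrays, 3 for each of 3 groups named in the labels. Con cells received phosphate-buffered saline, DOX cells 0.3 µM doxorubicin, and DOX_IFNg cells 0.3 µM doxorubicin with 20 ng/ml interferon gamma. The replicate numbers came from the same labels as the groups. Nothing in the labels said whether the replicates of a group were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The length of treatment was not given in the sources used here.

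The authors deposited 1 table of log2 expression values, with a value per transcript cluster (the probes grouped for 1 transcript) and array. Per the submitters' processing notes, RMA was used to make it. RMA is a routine that corrects background, normalizes arrays and summarizes probes, and its version and settings were not given in the sources used here. The log2 scale was inferred from the values, which lay between 2.29 and 19.9, and is not written in the table. Medians over all clusters lay between 4.08 and 4.17 on the 9 arrays, and the values were used without further normalization. RMA compresses differences between dim probes, so changes of dim genes can be understated. Changes near the upper end of the scale, where 324 values in 45 clusters lay at or above 19.9, can be understated as well. Pairs among Con replicate 1, the DOX arrays and DOX_IFNg replicates 1 and 2 held 82 to 186 exactly identical values. Each of these arrays had a maximum of 19.9315. Pairs with Con replicate 2, Con replicate 3 or DOX_IFNg replicate 3 held 1 to 17. This grouping of arrays was unevenly spread over the treatments, and its effect on the comparisons was not tested.

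The table held 65527 transcript clusters, of which 32493 were listed in the platform annotation. A single gene symbol was given for 30376 clusters and several symbols for 2117, while 33034 were not listed and are unnamed here. Clusters with a single symbol gave 30050 genes. Where a gene had more than 1 such cluster (245 genes), the cluster with the highest mean over all arrays stood for it. The RefSeq gene table of assembly GRCm38.p6 held 28940 of the symbols and was used only for gene types, with 18268 listed as protein coding. No coordinates were used. All columns of the table belonged to the 9 arrays. Pseudogene and gene family symbols can share probes with near-identical copies and are uncertain.

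Group means were fitted to all 9 arrays together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which left 6 residual and 2.41 prior degrees of freedom per gene. The comparisons were DOX minus Con, DOX_IFNg minus DOX and DOX_IFNg minus Con. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 30050 genes of a comparison, and a gene was called at an adjusted p under 0.05 with no filter on dim genes and no minimum fold. Every adjusted p given for a gene came from limma. The number of arrays limits the precision: the median gene had a 95% interval of ±0.19 on the log2 scale and the gene at the 95th percentile one of ±0.49. On simulated values for DOX_IFNg minus DOX over 30050 genes, the procedure called 70.1% of 67 genes changed by 0.5, 94.0% of 67 changed by 1 and 100% of 66 changed by 2 on the log2 scale, with 10 false calls among 186. The simulated noise was independent between genes, and the many changed genes eased the adjusted threshold. These shares therefore do not hold where few genes change. In the measured DOX_IFNg minus DOX, Cxcl1 differed by 0.54 (SE 0.095) at an adjusted p = 0.762.

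The groups, tests, gene lists and rule for named genes were fixed before the data were examined, as were the alternative settings except those described as added later. The text names, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose arrays did not overlap between the groups, leaving out predicted, clone, small RNA and antigen receptor symbols. It also names up to 4 called members of each list by size of change, and a set of genes reported in each comparison whether called or not. A gene of that set with no value below was not analysed here. The 31 lists covered p53 targets, G1/S and DNA replication, mitosis, apoptosis, pyroptosis and necroptosis, antioxidant response, unfolded protein and integrated stress response, iron handling and ferroptosis, autophagy and lysosome, anthracycline targets, and immediate early genes. They also covered interferon gamma signalling, interferon-inducible GTPases, antiviral interferon-stimulated genes, major histocompatibility complex (MHC) class I and class II presentation, chemokines and cytokines, and interferon-induced metabolic enzymes. Metabolic and cardiac lists held fatty acid oxidation, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, AMPK and p38 pathways, the sarcomere, cardiac calcium handling and ion channels, and cardiac transcription factors with natriuretic peptides. Markers of other cell types covered extracellular matrix and fibroblasts, immune cells, endothelium, and smooth muscle with pericytes, and a last list held reference genes. Some lists share members, such as 5 genes of the p53 and apoptosis lists and 5 of the antioxidant and iron lists.

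Each list was tested with camera of limma at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 31 lists of a comparison, and its calls were set beside camera with an estimated correlation and fry. Camera compares a list with all other genes, while fry tests whether the members move on balance one way. Members were also tested with p-values adjusted over the list alone. As a rough guide to detection, the 95th percentile of the mean level of 1539 olfactory, vomeronasal and trace amine receptor genes was used, at log2 4.72. This receptor limit was chosen after the data were seen, and 11916 genes (39.7%) lay above it. Probes of different genes are not on a common scale, so a level under the limit does not show that a gene was silent.

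The alternatives were a replicate block, a fit of only the 2 groups compared, 2 filters on dim genes, 2 other rules for genes with several clusters, centring on array medians, quantile normalization, trended and robust eBayes, array weights, a minimum of 2-fold, an adjusted p under 0.01, and leaving out each array in turn. A set of 3 further gene filters and the quantile-normalized list tests were added after the data were seen. Other splits of the 6 arrays of each comparison were fitted as well. Pairs of comparisons that share arrays were set beside 100 simulations of unchanged groups.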

Results

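The data were log2 expression values of 30050 genes on 9 arrays of cells that the labels name HL-1, 3 each of cells given phosphate-buffered saline (Con), 0.3 µM doxorubicin (DOX), or 0.3 µM doxorubicin with 20 ng/ml interferon gamma (DOX_IFNg). Doxorubicin is an anthracycline that traps topoisomerase II on DNA. Interferon gamma is a cytokine that signals through the receptor chains Ifngr1 and Ifngr2 and kinases that include Jak1. The first principal component held 60.1% of the variance and separated Con, with scores from -49.9 to -34.5, from all 6 treated arrays, with scores from 17.5 to 26.5. The second held 14.2%, and on it Con replicate 3 lay at -23.5 against 11.3 and 21.1 for the other Con arrays. DOX_IFNg replicate 1 also lay apart from its group on it, at 19.7 against 0.36 and -8.41. No arrays of cells given interferon gamma alone were analysed here, so its effect was compared only in the presence of doxorubicin.

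In control cells, probes of several heart muscle genes were dim. Myh6, the main myosin heavy chain of the adult mouse heart, lay at log2 4.29 ± 0.04 (SD, n = 3), Nppa, the atrial natriuretic peptide, at 3.97 ± 0.09, Myl7, an atrial myosin light chain, at 4.12 ± 0.06, and Gata4, a cardiac transcription factor, at 4.03 ± 0.07, all under the receptor limit of 4.72. Above it lay Nkx2-5, a cardiac transcription factor, at 5.39 ± 0.08, Tnnt2, cardiac troponin T, at 7.94 ± 0.18, Acta1, skeletal actin, at 8.41 ± 0.19, and Myog, a transcription factor of skeletal muscle differentiation, at 8.18 ± 0.19. Of the further skeletal muscle transcription factors, Myod1 lay above the limit at 6.03 ± 0.15 and Myf5 under it at 3.89 ± 0.04. Averaged over all arrays, 8 of 21 sarcomere genes, 7 of 20 calcium handling and ion channel genes and 10 of 15 cardiac transcription factor and natriuretic peptide genes lay above the limit, against 19 of 19 tricarboxylic acid cycle genes and 19 of 20 glycolysis genes. Of the interferon lists, 8 of 18 signalling genes, 1 of 14 GTPases, 0 of 30 antiviral genes, 7 of 16 class I genes and 0 of 9 class II genes lay above it. Ifngr2 lay at 5.13 ± 0.09 and Jak1 at 7.49 ± 0.06 in Con, while Ifngr1 lay at 4.20 ± 0.05. Immune markers lay above the limit in 1 of 15 cases and endothelial markers in 0 of 9, against 11 of 15 extracellular matrix and fibroblast markers.

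**Figure D1:**
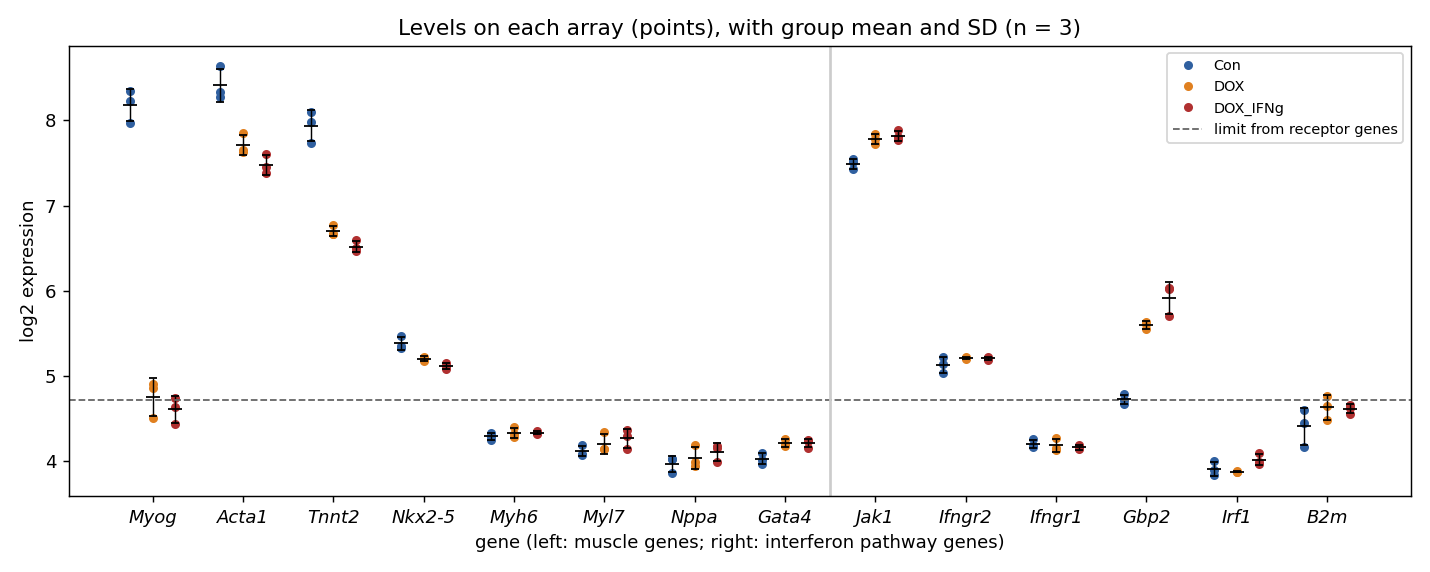
Log2 expression (vertical axis) of muscle genes (left) and interferon pathway genes (right) on each array, coloured by group, with the group mean and SD (n = 3) and the receptor limit of 4.72 as a dashed line. Myog lay at 8.18 in Con and at 4.76 in DOX, while Myh6, Myl7, Nppa, Gata4, Ifngr1 and Irf1 lay under the line in all groups.

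Doxorubicin-treated cells carried less RNA of cell division genes and more of p53 target genes than control cells. Plk1, a kinase of mitosis, fell by 2.79 on the log2 scale (SE 0.17, 3 arrays per group, adjusted p = 2.51e-05), and Mcm6, a subunit of the replicative helicase, fell by 2.63 (SE 0.10, adjusted p = 5.57e-06). Plk2, a stress-responsive kinase and p53 target, rose by 2.71 (SE 0.13, adjusted p = 9.05e-06), and Gadd45g, a growth arrest and stress gene, rose by 3.91 (SE 0.24, adjusted p = 2.63e-05). Myog fell by 3.42 (SE 0.14, adjusted p = 5.57e-06), from 8.18 ± 0.19 in Con to 4.76 ± 0.22 in DOX (SD, n = 3). In all, 2423 genes were called higher and 2264 lower, of which 324 and 327 changed at least 2-fold and 2137 and 1468 were protein coding. Of the 4687 called genes, 59.7% changed by less than 1.5-fold. The arrays of the groups did not overlap in 32.9% of all genes, where chance gives 10%.

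The largest rise was that of Pinlyp (4.82, SE 0.36, 28.3-fold). After Gadd45g came Lims2 (3.43), Atp6v1d, a subunit of the vacuolar ATPase (3.08), Mmp2, a secreted gelatinase (3.00), the transcription factor Klf10 (2.97), Id2, an inhibitor of basic helix-loop-helix factors (2.97), Abhd4 (2.72), Plk2 and the homeobox gene Hoxa5 (2.67). After Myog, the largest falls were those of S100a4, a calcium-binding protein (-3.03), Plk1, Mcm6, Rrm1, the large subunit of ribonucleotide reductase (-2.62), and the histone gene Hist1h2af (-2.57), whose control level of 19.6 lay near the top of the scale. Myog lay at 4.76 in DOX, close to the receptor limit of 4.72. The falls of Myog and Hist1h2af can thus be understated, and their ranks are uncertain. The clusters of Hist3h2bb-ps (-2.98), Pcna-ps2 (-2.89), Hmgn2-ps1 (-2.88) and Hmgn2l6 (-2.56) fell too, but they resemble parent genes, and which transcript they measured is uncertain.

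Of the 27 measured p53 targets, 15 rose and 12 did not pass the test, and 18 rose and 1 fell adjusted over the list alone. Besides Plk2, the largest rises were those of the receptor Eda2r (2.14), the cyclin Ccng1 (1.70) and Ei24 (1.40). By camera the list was higher at an adjusted p = 1.99e-09, and at an adjusted p = 0.0117 with an estimated correlation. Of 24 genes of G1/S and DNA replication, 20 fell, 1 rose and 3 did not pass, with Mcm6, Rrm1 and the helicase subunits Mcm5 (-2.27) and Mcm2 (-2.24) falling most. Adjusted over the list alone, 23 fell and 1 rose. The camera adjusted p was 1.02e-19, and adjusted p = 0.0199 with an estimated correlation. Of 24 mitosis genes, 20 fell and 4 did not pass, among them the kinesins Kif20a (-1.51) and Kif11 (-1.14) and the checkpoint kinase Bub1 (-1.24). Adjusted over the list alone, 22 fell and 1 rose. The camera adjusted p was 1.60e-15, and adjusted p = 0.0387 with an estimated correlation.

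Lists of stress responses were higher by camera with the preset correlation, but not with an estimated one. In the unfolded protein and integrated stress response list, 9 of 17 genes rose, 2 fell and 6 did not pass (10 and 3 adjusted over the list alone), led by the transcription factor Ddit3 (2.59), the glutathione-degrading Chac1 (1.57), Herpud1 (1.31) and asparagine synthetase Asns (1.14). Its camera adjusted p was 6.62e-05, and adjusted p = 0.211 with an estimated correlation. The antioxidant list had 9 of 17 genes higher and 8 not passing (12 higher and 1 lower adjusted over the list alone), with Nqo1 (1.57), the cystine transporter Slc7a11 (1.36), Gclc (1.21) and heme oxygenase Hmox1 (1.11). Its camera adjusted p was 1.45e-06, and adjusted p = 0.108 with an estimated correlation. Of the autophagy and lysosome genes, 9 of 16 rose and 7 did not pass (10 rose adjusted over the list alone), with the autophagy receptor Sqstm1 (2.57) and the cathepsins Ctsl (1.10) and Ctsb (1.09) leading. The camera adjusted p was 3.19e-07, and adjusted p = 0.122 with an estimated correlation. Of the immediate early genes, 9 of 18 rose and 9 did not pass (11 rose adjusted over the list alone), with Jun (0.95), Fosl1 (0.89) and Klf4 (0.88) leading. The camera adjusted p was 0.000135, and adjusted p = 0.211 with an estimated correlation. In the pyroptosis and necroptosis list, 5 of 11 rose and 6 did not pass (5 rose adjusted over the list alone), among them the inflammatory caspase Casp4 (1.35), Mlkl (0.69), Nlrp3 (0.48) and the pore former Gsdmd (0.46). The camera adjusted p was 0.00211, and adjusted p = 0.103 with an estimated correlation.

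The calls of 4 further lists were each lost when certain single arrays were left out. Oxidative phosphorylation was lower (adjusted p = 0.0262, and adjusted p = 0.660 with an estimated correlation), with 11 of 55 genes lower, 2 higher and 42 not passing, and 13 lower and 4 higher adjusted over the list alone. Cox6b1 fell by 1.69 and Atp5d by 0.68, while Cox6a2, the heart and skeletal muscle form of its subunit, rose by 0.74. Its call was lost without DOX replicate 3 (adjusted p = 0.158). Interferon-induced metabolic enzymes were higher (adjusted p = 0.0242, and adjusted p = 0.138 with an estimated correlation), with 2 of 9 genes higher and 7 not passing (3 higher adjusted over the list alone). These were Wars (1.12), a tryptophan tRNA synthetase, and Sat1 (0.94), an enzyme of polyamine breakdown, and the call was lost without Con replicate 1 (adjusted p = 0.0572). Iron handling and ferroptosis was higher (adjusted p = 0.0372, and adjusted p = 0.150 with an estimated correlation), with 5 of 14 genes higher, 3 lower and 6 not passing (7 and 3 adjusted over the list alone). Besides Slc7a11 and Hmox1, Slc3a2, the partner chain of Slc7a11, rose by 0.80 and the iron exporter Slc40a1 by 0.71, and the call was lost without Con replicate 1, Con replicate 3 or DOX replicate 2 (adjusted p up to 0.0591). Extracellular matrix and fibroblast markers were lower (adjusted p = 0.0380, and adjusted p = 0.367 with an estimated correlation), with 6 of 15 genes lower, 4 higher and 5 not passing (9 and 5 adjusted over the list alone). The collagens Col3a1 (-1.87) and Col1a2 (-1.03) fell while Mmp2 rose, and the call was lost without Con replicate 1, DOX replicate 3, DOX_IFNg replicate 1 or DOX_IFNg replicate 3 (adjusted p up to 0.0992). Quantile normalization also ended the calls of iron handling (adjusted p = 0.0687) and extracellular matrix (0.227), a filter on the dimmest genes those of oxidative phosphorylation (0.0731), iron handling (0.0975) and extracellular matrix (0.119), and the replicate block that of extracellular matrix (0.0681).

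Camera did not call the remaining 19 lists (adjusted p between 0.0677 and 0.998), and in 6 of them the median, mean and test differed in sign. Fry, which does not compare a list with other genes, called 9 of them. These were cardiac transcription factors and natriuretic peptides (adjusted p = 6.55e-05), apoptosis (0.000110), smooth muscle (0.000440), calcium handling (0.00171), the sarcomere (0.00291), anthracycline targets (0.00584), GTPases (0.0155), interferon signalling (0.0256) and fatty acid oxidation (0.0353). Without Con replicate 1 camera called apoptosis (adjusted p = 0.0481). Of the heart lists, the sarcomere had 3 genes lower and 1 higher of 21 (5 and 1 adjusted over the list alone), with Tnnt2 falling by 1.24. The call of Nexn was lost without DOX replicate 1 or DOX replicate 2 (adjusted p up to 0.0603). Des lost its call without Con replicate 1, Con replicate 2, DOX replicate 1 or DOX replicate 2 (adjusted p up to 0.0942). Calcium handling and ion channels had 5 lower and 1 higher of 20 (5 and 1 adjusted over the list alone), with the gap junction gene Gja5 (-1.25), Casq2 (-0.80) and the calcium pump Atp2a2 (-0.73). Cardiac transcription factors and natriuretic peptides had 5 of 15 lower (7 lower and 2 higher adjusted over the list alone), with Nr2f2 (-1.30), Acta1 (-0.70) and Srf (-0.49). Of the metabolic lists, fatty acid oxidation had 7 higher and 2 lower of 29, also adjusted over the list alone, with Hadhb (1.28) and Etfa (1.06). The tricarboxylic acid cycle had 2 higher and 3 lower of 19, also adjusted over the list alone, with Idh2 (-1.65) and Dld (0.87). Glycolysis had 3 higher and 6 lower of 20 (3 and 7 adjusted over the list alone), with Pfkm (-1.84), Pgk1 (-1.03) and Pfkfb3 (0.94). AMPK and p38 pathways had 3 higher and 3 lower of 20 (3 and 4 adjusted over the list alone), with Acaca, the target enzyme of AMPK in fatty acid synthesis, falling by 1.44. Its member Dusp10 lost its call without Con replicate 1, Con replicate 2, DOX replicate 1 or DOX replicate 3 (adjusted p up to 0.0711). Apoptosis had 5 higher and 2 lower of 22, also adjusted over the list alone, with the p53 target Pmaip1 (1.24) and Bcl2l1 (0.79). Anthracycline targets, transport and metabolism had 2 higher and 2 lower of 15, also adjusted over the list alone, with the drug efflux pumps Abcb1b (1.21) and Abcb1a (1.05) and topoisomerase Top2a (-1.13). Smooth muscle and pericyte markers had 3 of 8 lower, also adjusted over the list alone, with Cnn1 (-1.29). Reference genes had 1 higher and 1 lower of 8, also adjusted over the list alone, namely Hprt (0.71) and Pgk1.

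Interferon lists not called by camera in DOX minus Con had the following called members. Signalling had 2 of 18 higher, also adjusted over the list alone, namely Irf7 (0.50) and Jak1 (0.29), and fry called the list (adjusted p = 0.0256), as it did the GTPases (0.0155). Class I presentation had 2 higher and 3 lower of 16, also adjusted over the list alone, with the peptide transporter Tap1 (0.40). Its lower members were Erap1, Psmb10 and Calr. Erap1 lost its call without any single array other than Con replicate 3 (adjusted p up to 0.132). Psmb10 lost it without Con replicate 2, Con replicate 3 or any single DOX array (adjusted p up to 0.0941), and Calr lost it under quantile normalization (-0.06, adjusted p = 0.631). Chemokines and cytokines had 3 higher and 1 lower of 26, also adjusted over the list alone, with Il6 (0.64), Lif (0.58) and Csf1 (0.54). The lower member Cxcl12 lost its call without any single array other than Con replicate 3 or DOX_IFNg replicate 1 (adjusted p up to 0.120). Of the 14 GTPases, Gbp2 rose by 0.87 (SE 0.09) and Gbp7 by 0.23, also adjusted over the list alone, but the call of Gbp7 was lost without Con replicate 1, Con replicate 3, DOX replicate 1 or DOX replicate 3 (adjusted p up to 0.0915). Of the 30 antiviral genes, Eif2ak2 alone was called (0.21, adjusted p = 0.0497), not adjusted over the list alone, and it was lost in each fit that left out 1 array other than Con replicate 2 (adjusted p up to 0.165). The immune marker Cd14 (0.25, adjusted p = 0.0483), the only call among 15, was likewise not called adjusted over the list alone and was lost without Con replicate 1, Con replicate 2, DOX replicate 1, DOX replicate 2 or any single DOX_IFNg array (adjusted p up to 0.140). The replicate block also ended the calls of Gbp7 (adjusted p = 0.0570), Eif2ak2 (0.0893) and Cd14 (0.0971). By limma 0 of 9 class II genes and 0 of 9 endothelial markers were called, with 0 in each at an unadjusted p under 0.05, and fry gave adjusted p of 0.337 and 0.904 for these lists.

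Among the genes reported whether called or not, Mdm2, the p53-induced ubiquitin ligase, rose by 0.64 (SE 0.09, adjusted p = 0.00168) and Prkaa2, a catalytic subunit of AMPK, by 0.59 (SE 0.09, adjusted p = 0.00307). Cdkn1a, the cyclin-dependent kinase inhibitor p21, lay 0.37 higher (SE 0.14), which did not pass (adjusted p = 0.118). It was called in a fit of only DOX and Con (adjusted p = 0.0102) and without DOX_IFNg replicate 3 (adjusted p = 0.00844). The SD of Cdkn1a was 0.32 in DOX_IFNg against 0.01 in Con and 0.08 in DOX. Top2b, the topoisomerase II of non-dividing cells, differed by -0.41 (SE 0.28, adjusted p = 0.409). Mapk14 fell by 0.21 (SE 0.05, adjusted p = 0.0204), a call lost without Con replicate 2, Con replicate 3, DOX replicate 1 or DOX replicate 3 (adjusted p between 0.0531 and 0.0800). Irf1 (-0.03), Cxcl10 (-0.15), Cd274 (-0.03), Ppargc1a (0.25), Cpt1b (-0.13), Nppa (0.07), Nppb (-0.09), Myh6 (0.04), Ifngr1 (-0.01) and Ifngr2 (0.08) were not called, with adjusted p between 0.0863 and 0.913. Among protein-coding genes only, a setting added after the data were seen, Cxcl10 was called (adjusted p = 0.0484).

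**Figure D2:**
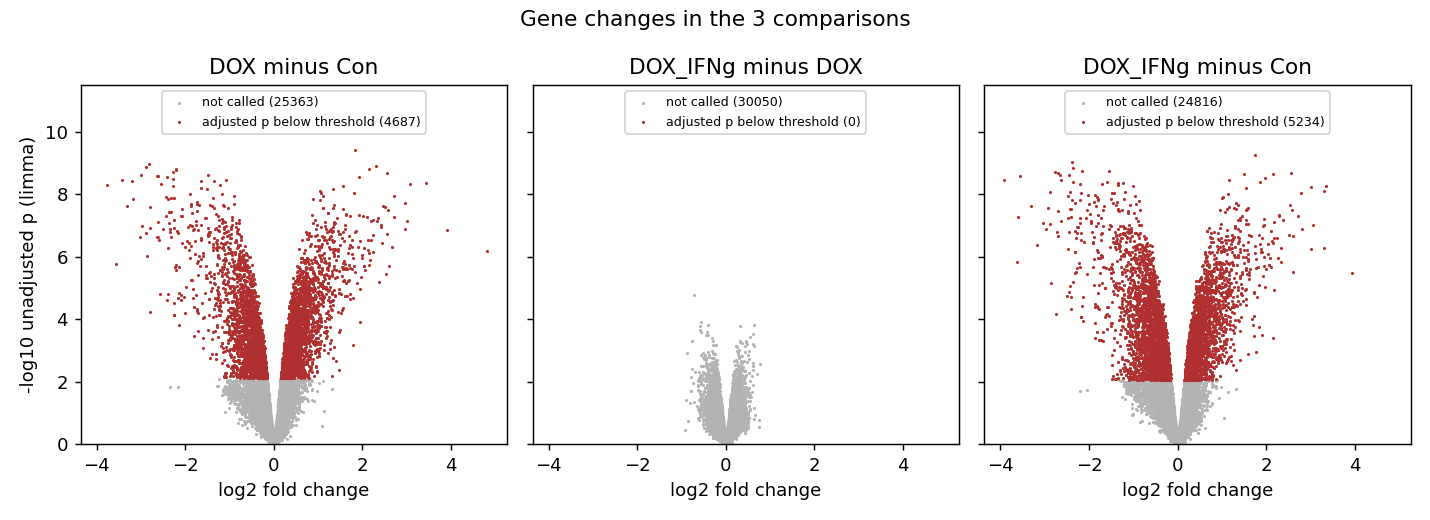
Log2 fold change (horizontal axis) and -log10 of the unadjusted limma p (vertical axis) of each of the 30050 genes in the 3 comparisons, with called genes in red and the others in grey. The red points number 4687 in DOX minus Con, 0 in DOX_IFNg minus DOX and 5234 in DOX_IFNg minus Con.

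Adding interferon gamma to doxorubicin was followed by no called change, including in genes known to respond to this cytokine. Gbp2, an interferon-inducible GTPase, lay at 5.92 ± 0.19 in DOX_IFNg and 5.60 ± 0.04 in DOX (SD, n = 3), a difference of 0.32 (SE 0.09, adjusted p = 0.966). Irf1, a transcription factor induced early by interferon gamma, lay at 4.02 ± 0.07 against 3.88 ± 0.01, a difference of 0.14 (SE 0.06, adjusted p = 0.976), under the receptor limit in both groups. The chemokine Cxcl10 differed by 0.05 and the checkpoint ligand Cd274 by 0.01, both under the receptor limit as well. Across the 87 measured genes of the lists for interferon signalling, GTPases, antiviral genes and class I and class II presentation, differences ran from -0.25 to 0.32, and the highest upper limit of a 95% interval was 0.60, for Samd9l. Only 16 of the 87 lay above the receptor limit, and rises of the others can be understated, so their narrow intervals do not show a lack of response. An unadjusted p under 0.05 was reached by 5 of the 87, where chance gives 4.35: Irf1, Irf2, Gbp2 and Gbp9 were higher and Psmb10 lower.

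Limma called 0 genes higher and 0 lower in DOX_IFNg than in DOX. At an unadjusted p under 0.05 there were 597 higher and 906 lower, 1503 in all, where chance gives 1502.5. That number depended on the setting, with 2546 (8.47%) under array weights, 2100 (6.99%) without DOX_IFNg replicate 3 and 1114 (3.71%) without DOX replicate 2. The smallest adjusted p was 0.506, log2 differences ran from -0.92 to 0.78, and the arrays of the groups did not overlap in 11.2% of genes, where chance gives 10%. Trended and robust eBayes, array weights and the replicate block also called 0 genes. Without Con replicate 3, which entered only the estimate of spread, 1 gene was called, the olfactory receptor Olfr1208 (-0.72, adjusted p = 0.0156), named here after its values were seen.

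By camera with the preset correlation 6 of the 31 lists were called in DOX_IFNg minus DOX, but 0 with an estimated correlation and 0 by fry, which tests 1 direction, while fry's test for change in either direction called the chemokine list (adjusted p = 0.0375). Oxidative phosphorylation was lower (median -0.09, camera adjusted p = 5.42e-05, and adjusted p = 0.527 with an estimated correlation), a preset call kept without each single array (adjusted p up to 0.0281). Proteasome subunits (median -0.11, camera adjusted p = 0.000105) and ribosomal proteins (median -0.08, camera adjusted p = 0.000223), families chosen after their values were seen, were lower as well, both at an adjusted p = 0.641 with an estimated correlation. Chemokines and cytokines were higher (adjusted p = 0.00671, and adjusted p = 0.527 with an estimated correlation), a call lost without DOX_IFNg replicate 1 or DOX_IFNg replicate 3 (adjusted p up to 0.0658). Immediate early genes were lower (adjusted p = 0.00136, and adjusted p = 0.527 with an estimated correlation), a call lost without DOX replicate 1 (adjusted p = 0.102). Fatty acid oxidation was lower (adjusted p = 0.0172, and adjusted p = 0.527 with an estimated correlation), a call lost without DOX replicate 2, DOX_IFNg replicate 1 or DOX_IFNg replicate 2 (adjusted p up to 0.133). Glycolysis was lower (adjusted p = 0.0292, and adjusted p = 0.563 with an estimated correlation), a call lost without DOX replicate 1, DOX replicate 2, DOX_IFNg replicate 1 or DOX_IFNg replicate 2 (adjusted p up to 0.315). Smooth muscle markers were lower (adjusted p = 0.0172, and adjusted p = 0.527 with an estimated correlation), a call lost without DOX replicate 1, DOX replicate 2, DOX_IFNg replicate 2 or DOX_IFNg replicate 3 (adjusted p up to 0.131). Quantile normalization also ended the calls of glycolysis (adjusted p = 0.147) and smooth muscle markers (0.162), as did a filter on the dimmest genes (0.0725 and 0.0792). The remaining 25 lists, those of interferon signalling, GTPases, antiviral genes and presentation among them, had camera adjusted p between 0.0793 and 0.925, and in 2 of them the median, mean and test differed in sign. Without DOX replicate 3 camera called GTPases (adjusted p = 0.0426), the tricarboxylic acid cycle (0.0200), autophagy and lysosome (0.00854) and the antioxidant list (0.00739), and without DOX replicate 2 mitosis (0.0379). For GTPases the adjusted p without any other single array lay between 0.144 and 0.688. Adjusted over the list alone, 4 genes passed: the chemokines Cxcl1 (0.54) and Ccl2 (0.33) at 0.00680, and the immediate early genes Egr1 (-0.43) and Ccn1 (-0.37) at 0.0313. Over all genes their adjusted p was 0.762 or above, and both chemokines lay under the receptor limit.

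None of the remaining genes reported whether called or not was called by limma between DOX_IFNg and DOX. Cdkn1a differed by 0.13, Mdm2 by 0.11, Top2a by 0.15, Top2b by 0.23, Prkaa2 by 0.14, Mapk14 by -0.11, Ppargc1a by 0.05, Cpt1b by 0.05, Nppa by 0.07, Nppb by -0.02, Myh6 by 0.00, Ifngr1 by -0.03 and Ifngr2 by 0.00 on the log2 scale. Their limma adjusted p lay between 0.976 and 0.999. The 95% interval was widest for Top2b, from -0.40 to 0.86, and reached 0.44 for Cdkn1a, so changes of that size were not excluded for these genes.

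**Figure D3:**
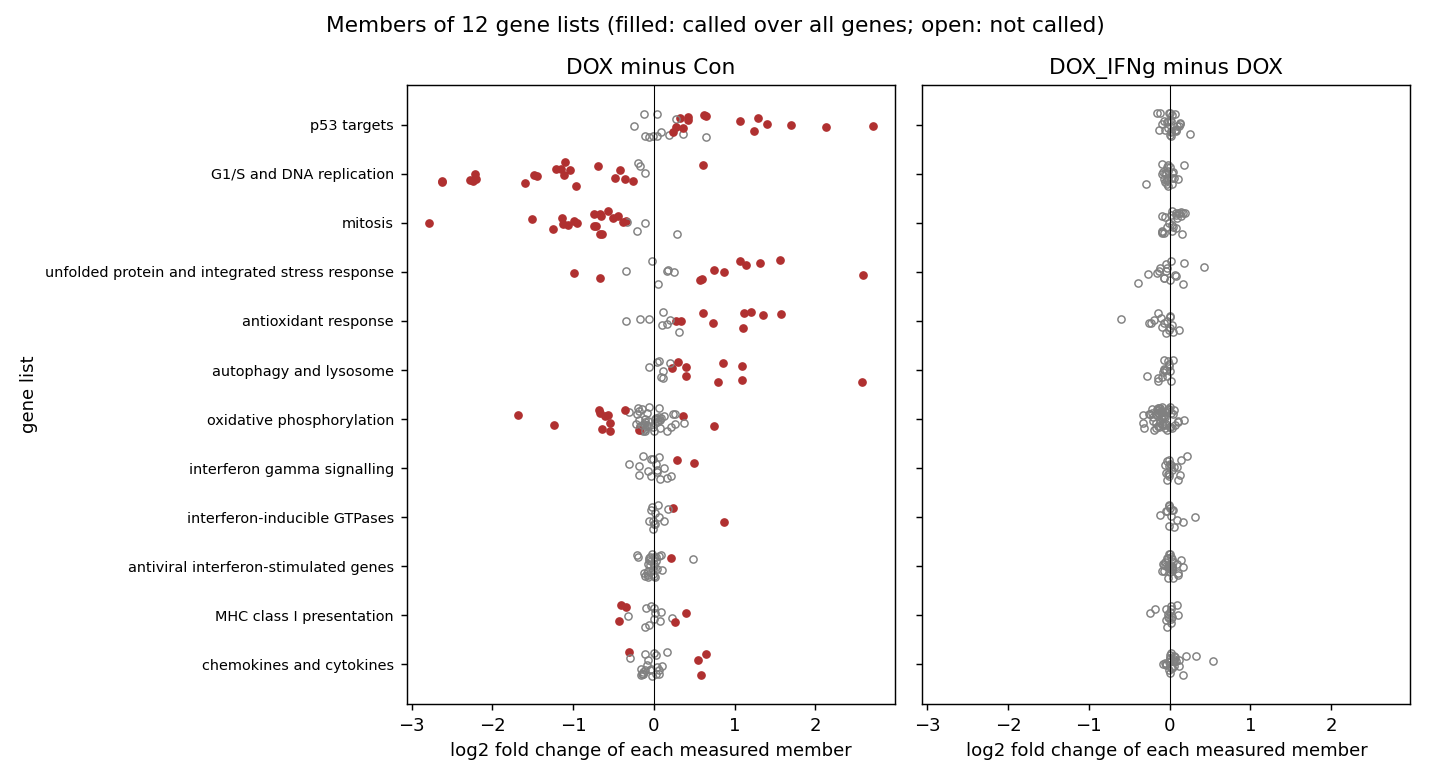
Log2 fold change (horizontal axis) of each measured member of 12 gene lists (vertical axis) in DOX minus Con (left) and DOX_IFNg minus DOX (right), 1 point per gene, filled red where limma called the gene over all genes and open where it did not. In DOX minus Con the p53 targets reach 2.71 and the mitosis genes -2.79, while all points of DOX_IFNg minus DOX are open.

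Cells given both agents also carried less RNA of cell division genes and more of p53 target genes than control cells. Plk1 fell by 2.88 (SE 0.17, adjusted p = 2.23e-05), and Mcm6 fell by 2.70 (SE 0.10, adjusted p = 5.74e-06). Plk2 rose by 2.79 (SE 0.13, adjusted p = 7.57e-06), and the stress response factor Ddit3 rose by 3.02 (SE 0.23, adjusted p = 5.75e-05). Gbp2 rose by 1.19 (SE 0.09, adjusted p = 5.75e-05), from 4.73 ± 0.05 in Con to 5.92 ± 0.19 in DOX_IFNg (SD, n = 3). In all, 2407 genes were called higher and 2827 lower, of which 325 and 440 changed at least 2-fold. Quantile normalization turned this balance, with 2903 called higher and 2445 lower. Groups did not overlap in 33.0% of genes, where chance gives 10%. Besides Plk2 and Ddit3, the largest rises were those of Pinlyp (3.93, SE 0.36), Lims2 (3.34), Gadd45g (3.32), Klf10 (3.30), Id2 (3.06), Atp6v1d (3.00), Mmp2 (2.80) and Abhd4 (2.73). The largest falls were those of S100a4 (-3.61), Myog (-3.57), Plk1, Hist1h2af (-2.87), Mcm6 and Rrm1 (-2.65), with the uncertain clusters Hist3h2bb-ps (-3.05), Hmgn2-ps1 (-2.98), Pcna-ps2 (-2.77) and Hmgn2l6 (-2.64). Myog lay at 4.61 in DOX_IFNg, under the receptor limit, and Hist1h2af lay at 19.6 in Con, near the top of the scale, so their falls can be understated and their ranks are uncertain.

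Of the lists in DOX_IFNg minus Con, 14 were called by camera. The p53 targets had 16 of 27 genes higher and 11 not passing (19 higher and 1 lower adjusted over the list alone), with Eda2r (2.27), Ccng1 (1.74) and Trp53inp1 (1.54) besides Plk2, at an adjusted p = 1.11e-09, and an adjusted p = 0.0109 with an estimated correlation. G1/S and DNA replication had 20 of 24 lower, 1 higher and 3 not passing (23 and 1 adjusted over the list alone), at an adjusted p = 5.61e-19, and an adjusted p = 0.0220 with an estimated correlation. Mitosis had 19 of 24 lower, 1 higher and 4 not passing (20 and 1 adjusted over the list alone), with Kif20a (-1.60), at an adjusted p = 8.49e-13, and an adjusted p = 0.0618 with an estimated correlation. Oxidative phosphorylation had 18 of 55 lower, 1 higher and 36 not passing (23 and 1 adjusted over the list alone), with Cox6b1 (-1.90), at an adjusted p = 1.97e-05, and an adjusted p = 0.272 with an estimated correlation. Autophagy and lysosome had 7 of 16 higher and 9 not passing (8 higher adjusted over the list alone), with Sqstm1 (2.59), at an adjusted p = 1.97e-05, and an adjusted p = 0.145 with an estimated correlation. Unfolded protein and integrated stress response had 10 of 17 higher, 2 lower and 5 not passing (11 and 2 adjusted over the list alone), at an adjusted p = 0.000132, and an adjusted p = 0.220 with an estimated correlation. The antioxidant list had 8 of 17 higher, 2 lower and 7 not passing (11 and 2 adjusted over the list alone), with Slc7a11 (1.47), at an adjusted p = 0.000105, and an adjusted p = 0.141 with an estimated correlation. Pyroptosis and necroptosis had 4 of 11 higher and 7 not passing, also adjusted over the list alone, with Casp4 (1.47), at an adjusted p = 0.00876, and an adjusted p = 0.141 with an estimated correlation. Iron handling and ferroptosis had 5 of 14 higher, 2 lower and 7 not passing (6 and 3 adjusted over the list alone), at an adjusted p = 0.0307, and an adjusted p = 0.141 with an estimated correlation, a call ended by a filter on the dimmest genes (0.0597). Smooth muscle and pericyte markers had 3 of 8 lower and 5 not passing (4 lower adjusted over the list alone), with Cnn1 (-1.40), at an adjusted p = 0.0203, and an adjusted p = 0.141 with an estimated correlation, a call ended by quantile normalization (0.274).

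Another 4 calls in DOX_IFNg minus Con were each lost when certain single arrays were left out. Glycolysis was lower (8 lower and 3 higher of 20, 9 and 3 adjusted over the list alone, adjusted p = 0.0307, and adjusted p = 0.534 with an estimated correlation), a call lost without DOX_IFNg replicate 1 (adjusted p = 0.0673). Apoptosis was higher (6 higher and 2 lower of 22, 7 and 2 adjusted over the list alone, adjusted p = 0.0347, and adjusted p = 0.141 with an estimated correlation), a call lost without Con replicate 3 (adjusted p = 0.0651). Immediate early genes were higher (5 higher and 2 lower of 18, 8 and 3 adjusted over the list alone, adjusted p = 0.0401, and adjusted p = 0.475 with an estimated correlation), a call lost without Con replicate 1 or DOX_IFNg replicate 3 (adjusted p up to 0.153). Interferon-inducible GTPases were higher (adjusted p = 0.0401, and adjusted p = 0.212 with an estimated correlation) with Gbp2 alone called among 14, also adjusted over the list alone, and the list call was lost without Con replicate 2, DOX_IFNg replicate 1 or DOX_IFNg replicate 2 (adjusted p up to 0.0789). Quantile normalization also ended the calls of apoptosis (adjusted p = 0.0631), GTPases and immediate early genes (both 0.0508), a filter on the dimmest genes those of apoptosis (0.0642) and immediate early genes (0.0550), and fry did not call the immediate early genes (0.0622).

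The other 17 lists had camera adjusted p between 0.0625 and 0.973 in DOX_IFNg minus Con, and in 4 of them the median, mean and test differed in sign. Fry called 8 of them. These were cardiac transcription factors and natriuretic peptides (adjusted p = 1.58e-05), extracellular matrix (0.000266), calcium handling (0.00110), interferon-induced metabolic enzymes (0.00166), interferon signalling (0.00236), the sarcomere (0.00377), anthracycline targets (0.00431) and AMPK and p38 pathways (0.00605). Without Con replicate 3 camera called extracellular matrix (adjusted p = 0.0237), cardiac transcription factors (0.0490) and interferon-induced metabolic enzymes (0.0491). Extracellular matrix and fibroblast markers had 4 higher and 8 lower of 15 (5 and 9 adjusted over the list alone), with Mmp2 and Col3a1 (-2.02). Of the heart lists, cardiac transcription factors and natriuretic peptides had 1 higher and 7 lower of 15 (2 and 7 adjusted over the list alone), with Acta1 (-0.93). Calcium handling and ion channels had 1 higher and 5 lower of 20 (1 and 6 adjusted over the list alone), and the sarcomere 3 lower of 21, also adjusted over the list alone, with Tnnt2 (-1.42). Fatty acid oxidation had 6 higher and 2 lower of 29 (7 and 2 adjusted over the list alone), with Hadhb (1.27). The tricarboxylic acid cycle had 2 higher and 4 lower of 19, also adjusted over the list alone, with Idh2 (-1.79). AMPK and p38 pathways had 3 higher and 5 lower of 20 (4 and 6 adjusted over the list alone), with Acaca (-1.53). Anthracycline targets had 2 higher and 2 lower of 15 (3 and 3 adjusted over the list alone), with Abcb1b (1.35), and reference genes 1 higher and 1 lower of 8, also adjusted over the list alone. Chemokines and cytokines had 5 higher and 1 lower of 26 (6 and 1 adjusted over the list alone), with Csf1 (0.71). Interferon signalling had 3 of 18 higher, interferon-induced metabolic enzymes 2 of 9 higher and class I presentation 2 higher and 3 lower of 16, each also adjusted over the list alone. Among these, Ptpn2 lost its call without Con replicate 1, Con replicate 3, DOX replicate 1, DOX replicate 2, DOX_IFNg replicate 1 or DOX_IFNg replicate 2 (adjusted p up to 0.106). Psme1 lost it without DOX_IFNg replicate 1 or DOX_IFNg replicate 2 (adjusted p up to 0.0818), and Calr lost it without Con replicate 2, Con replicate 3, DOX replicate 1, DOX_IFNg replicate 1 or DOX_IFNg replicate 2 (adjusted p up to 0.122). The antiviral list had 1 of 30 genes called, Eif2ak2 (0.24), not adjusted over the list alone, a call lost without Con replicate 1 or any single DOX_IFNg array (adjusted p up to 0.0814) and with the replicate block (0.0549), which also ended the call of Calr (0.0550). Limma called 0 of 9 class II genes, 0 of 15 immune markers and 0 of 9 endothelial markers, with 1, 0 and 0 at an unadjusted p under 0.05, and fry gave adjusted p of 0.767, 0.443 and 0.767.

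Among genes reported whether called or not, Mdm2 (0.75), Prkaa2 (0.72), Top2a (-0.98) and Mapk14 (-0.31) were called. Cdkn1a lay 0.50 higher (adjusted p = 0.0383), a call lost in each fit that left out 1 array other than DOX_IFNg replicate 1 or DOX_IFNg replicate 3 (adjusted p between 0.0560 and 0.0982). Irf1 (0.11), Cxcl10 (-0.10), Cd274 (-0.02), Top2b (-0.17), Ppargc1a (0.29), Cpt1b (-0.08), Nppa (0.14), Nppb (-0.12), Myh6 (0.05), Ifngr1 (-0.04) and Ifngr2 (0.08) were not called.

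Both comparisons against Con used the same control arrays and shared part of their called genes. Of the called genes, 1973 were higher in both and 2006 lower in both, where independent lists give 194 and 213. Of the genes limma called in both, 0 had opposite directions, where independent lists give 409. Shared controls and 0 called genes in DOX_IFNg minus DOX left little room for opposite calls, so this 0 adds no evidence of its own. Across genes, which are not independent replicates, the fold changes had r = 0.94, against 0.50 in simulated unchanged groups that share the controls. No split of the 3 controls leaves 2 on each side, so part of the excess of shared genes and of r may come from the shared controls. The covariance, to which shared controls add the same amount with or without effects, was 0.120 against 0.00672 simulated, a difference of 0.113. The simulations gave every group the same spread per gene, so their values are approximate. The SD of the difference across genes was 0.187 to 0.303 between Con arrays and 0.172 to 0.203 between DOX arrays. Values simulated for shared controls can therefore be too low. Between DOX minus Con and DOX_IFNg minus DOX, which share the DOX arrays with opposite sign, r was -0.07 against -0.50 simulated, with a covariance of -0.00321 against -0.00671. Since limma called 0 genes in the second of these, 0 genes were called in both steps, in the same or in opposite directions. Genes higher in DOX differed by a median of -0.04 and genes lower in DOX by a median of -0.02 when interferon gamma was added.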

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

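The tests of transcript clusters outside the named genes were chosen only after the data were seen. These clusters entered no comparison above and were looked at because the platform annotation either does not list them or gives them several symbols. Among 33034 clusters not listed, limma over all 65527 clusters called 157 higher and 468 lower in DOX minus Con, and 168 higher and 543 lower in DOX_IFNg minus Con. Among 2117 clusters with several symbols, 60 were higher and 112 lower in DOX minus Con, and 74 were higher and 130 lower in DOX_IFNg minus Con. In DOX_IFNg minus DOX limma called 0 clusters of either kind, and over all clusters 2848 had an unadjusted p under 0.05 (4.35%). Of the clusters with several symbols, 11 held genes of the interferon lists, and their differences in DOX_IFNg minus DOX ran from -0.04 to 0.09, with 0 called by limma, 0 at an unadjusted p under 0.05 and a highest upper limit of 0.33. The median level of clusters not listed was log2 3.92. No explanation was tested for these clusters.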

How the results depend on the processing

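Alternatives chosen only after the data were seen were the tests on protein-coding genes, on genes above the receptor limit, on all transcript clusters, and the quantile-normalized list tests. Gene counts kept within 1.5 times of those reported except under stricter thresholds, whose construction gives fewer genes. At least 2-fold left 324 higher and 327 lower in DOX minus Con and 325 and 440 in DOX_IFNg minus Con, and an adjusted p under 0.01 left 1471 and 1316, and 1397 and 1642. Leaving out 1 array gave 1749 to 2381 higher and 1580 to 2249 lower in DOX minus Con, and 1682 to 2300 and 2049 to 2892 in DOX_IFNg minus Con. In DOX_IFNg minus DOX it gave 0 to 0 higher and 0 to 1 lower, and 0 to 1 genes called in both steps in opposite directions and 0 to 0 in the same. The 1 gene came without Con replicate 3, the array farthest from its group and with the lowest weight (0.390), and the smallest adjusted p over all settings ranged from 0.0156 to 1.00. Quantile normalization turned the balance of DOX_IFNg minus Con from 46.0% to 54.3% higher calls.

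List calls depended on the form of the test, and not only through the correlation between genes. For pyroptosis and necroptosis in DOX minus Con the estimated correlation was 0.00944, under the preset 0.01. Its unadjusted camera p still rose from 0.000544 with the preset to 0.0134 with the estimate. For p53 targets, estimated at -0.000381, the unadjusted camera p rose from 1.92e-10 to 0.000378. With an estimated correlation 3, 0 and 2 lists were called in DOX minus Con, DOX_IFNg minus DOX and DOX_IFNg minus Con, and by fry 21, 0 and 21, against 12, 6 and 14 reported. Leaving out 1 array gave 10 to 12, 3 to 10 and 12 to 16, with 3 in DOX_IFNg minus DOX without DOX replicate 1, DOX_IFNg replicate 1 or DOX_IFNg replicate 2 and 10 without DOX replicate 3. Quantile normalization gave 10, 4 and 10. Of named genes, 18 of 115 calls in DOX minus Con and 14 of 112 in DOX_IFNg minus Con were lost under some setting. Calr in DOX_IFNg minus Con changed sign, from -0.24 to 0.14, under quantile normalization, and the cause was not tested.

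The replicate numbers did not pair the arrays throughout: same-numbered arrays had correlations of deviations from -0.16 to 0.36 over 9 pairs, 3 of them over 0.1, and 5 of 18 best matches were with their own number. Arrays of different numbers had correlations from -0.40 to 0.28. The highest values were those of Con replicate 1 with DOX_IFNg replicate 1 (0.36) and Con replicate 3 with DOX_IFNg replicate 3 (0.33). Shared handling of some same-numbered arrays therefore stays open. With the replicate block 2270 and 2202 genes were called in DOX minus Con, 0 and 0 in DOX_IFNg minus DOX, and 2293 and 2695 in DOX_IFNg minus Con, with 11, 6 and 14 lists. The block ended the call of extracellular matrix and fibroblast markers (adjusted p = 0.0681, against 0.00858 to 0.0992 leaving out 1 array) and, among named genes, of Gbp7, Eif2ak2 and Cd14 in DOX minus Con and Calr and Eif2ak2 in DOX_IFNg minus Con. A larger pseudocount was not run because the values were already log2. Of the 30050 genes, 39.7% lay above the receptor limit, so dim genes limit what could be seen.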

Other observations

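Chosen only after the values were seen were the tests of the 9 gene families, the test of skeletal muscle markers, the interval test limited to members above the receptor limit, the receptor limit and the lists of ubiquitous genes. In DOX minus Con, 12 of 16 measured genes of cholesterol synthesis fell, among them Fdps, Hmgcs1, Fdft1, Cyp51, Insig1 and Sqle (camera adjusted p = 2.27e-10 over the 9 families, and adjusted p = 0.00681 with an estimated correlation). Histone genes fell in 21 of 39 cases, led by Hist1h2af, though close copies make single members uncertain (camera adjusted p = 2.65e-12, and adjusted p = 0.0196 with an estimated correlation). Aminoacyl-tRNA synthetases, which load amino acids onto their tRNAs, rose in 11 of 16 cases, among them Cars, Gars, Eprs and Nars (camera adjusted p = 2.33e-10, and adjusted p = 0.0626 with an estimated correlation). Subunits of the vacuolar ATPase, which acidifies lysosomes, rose in 11 of 21 cases, led by Atp6v1d, Atp6v0d1 and Atp6v1h (camera adjusted p = 1.18e-08, and adjusted p = 0.0598 with an estimated correlation). Collagens were lower in 11 and higher in 1 of 42 cases (camera adjusted p = 7.42e-07, and adjusted p = 0.0790 with an estimated correlation). Proteasome subunits were lower in 11 and higher in 2 of 38 cases (camera adjusted p = 0.00555, and adjusted p = 0.339 with an estimated correlation) and tubulins lower in 6 and higher in 1 of 20 (camera adjusted p = 0.0218, and adjusted p = 0.339 with an estimated correlation). The directions of these 7 families held as deposited, with arrays centred on their medians and under quantile normalization. Ribosomal proteins were lower in 5 of 42 cases as deposited (camera adjusted p = 0.0212, and adjusted p = 0.461 with an estimated correlation), but higher in 6 and lower in 4 under quantile normalization. Hox genes were higher in 4 and lower in 2 of 33 cases with no call of the family (camera adjusted p = 0.988), whose camera direction turned under quantile normalization.

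For the absence of called genes in DOX_IFNg minus DOX, too little precision with 3 arrays per group to see a 2-fold rise is argued against only for the 16 members of the interferon signalling, GTPase, antiviral and class I lists above the receptor limit, whose 95% intervals reached at most 0.52, for Gbp2. Smaller rises missed for lack of precision stay open, and the interval of Gbp2 ran from 0.11 to 0.52. These members were 8 signalling genes, among them the receptor chain Ifngr2 and the kinase Jak1, 7 class I genes, 1 of 14 GTPases and 0 of 30 antiviral genes. The test thus covers few of the inducible genes. Of all 78 members the share whose interval excluded a 2-fold rise was 1, but the 62 under the limit, where RMA compresses differences, leave too little precision open. Exchanged arrays were predicted to make another split of the 6 arrays call genes, and the most genes called by another split was 0. This count cannot decide, since a correct split can also call 0 genes where few genes change. The split with DOX replicate 1, DOX replicate 2 and DOX_IFNg replicate 3 on 1 side gave 2513 genes at an unadjusted limma p under 0.05. The real split gave 1503. On the second principal component these arrays lay at -9.07, -11.6 and -8.41. DOX replicate 3 lay at 0.06, DOX_IFNg replicate 1 at 19.7 and DOX_IFNg replicate 2 at 0.36. An exchange thus stays open, and its test also needs arrays that could register the response. Probes that measure this RNA poorly stay open, because 0.806 of the ubiquitous, faster evolving genes lay above the receptor limit (25 of 31, 95% interval 0.625 to 0.925), and only 16 of the 87 interferon list members did. Cells that respond weakly to interferon gamma, a treatment too short or long before harvest, or inactive cytokine could not be tested with these arrays.

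Dim heart muscle genes beside a bright Myog are a pattern across probes that are not on a common scale, so it is a rough guide and does not show that a heart gene was silent. Weak signal of all genes is argued against, since the share of ubiquitous, slowly evolving genes above the receptor limit was 1 (23 of 23 measured, 95% interval 0.852 to 1), as it was for 19 of 19 genes of the tricarboxylic acid cycle, although only 23 of the 35 genes of the first list were measured. RNA that matches the mouse probes poorly in part of the genes stays open, since the shares of slowly and faster evolving ubiquitous genes above the limit differed by 0.194 (95% interval 0.0180 to 0.363). A candidate explanation is cells of a skeletal muscle kind. The share of skeletal markers above the limit exceeded that of the heart lists by 0.0721 (14 of 27 against 25 of 56, 95% interval -0.149 to 0.285, Fisher's exact test, two-sided p = 0.640). The heart lists hold genes that are not confined to heart muscle, such as the skeletal actin Acta1, so similar shares do not argue against skeletal muscle cells. The list of skeletal markers was written after the levels of Myog, Myod1, Acta1 and several of its other members were seen and it shares 1 member with the heart lists, and the lists of ubiquitous genes were written after the levels of Actb, Gapdh, B2m and H2-K1 were seen, so the test cannot decide, and the identity of the cells remains open.

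Other splits of the 6 arrays are too few for a share under 0.05, since 10 splits give at least 0.1. In DOX minus Con 1 of the 10 splits, the real one, gave as many genes (4687, highest other 0), and in DOX_IFNg minus Con likewise 1 of 10 (5234, highest other 0). In DOX_IFNg minus DOX all 10 of 10 splits gave as many genes, since the real count was 0 and the highest other 0.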
